A study of Homo sapiens with 8 samples.

How the data were processed

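The data are RNA sequencing of 8 libraries from TOV112D cells, an established human ovarian carcinoma line, in 4 groups of 2 libraries. Cells were transfected at 80% confluence with an empty vector, wild-type EZH2, T372A EZH2 or T372E EZH2 and collected after 72 h, per the labels. The column headers of the deposited table call the control cells GFP-overexpressing and the EZH2 forms GFP-tagged, whereas the labels speak of an empty vector. Groups and library numbers were taken from the labels, and each column was matched to its library by name. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

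The authors deposited RPKM values, that is reads per kilobase of gene scaled to library size, with 1 column per library and no pooling. The submitters' processing notes name CASAVA 1.8.2, Trimmomatic 0.32, TopHat2 2.0.10, DESeq2 1.10.0 and R 3.2.1, and genome build hg19, also called GRCh37. They do not say in which order the tools were used, and the read counter, its strand setting and the annotation release are not given in the sources used here. Reads from overlapping or antisense genes therefore cannot be told apart, and genes with near-identical copies, such as nuclear copies of mitochondrial genes and ribosomal protein genes with pseudogenes, have uncertain values. RPKM also cannot separate plasmid from endogenous EZH2 transcripts. The table pairs versioned Ensembl identifiers with symbols, gene types and coordinates, which are given here as in the table on hg19. Tables of the authors' own tests were not analysed here.

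Low values of a gene were whole multiples of a single step, which gave the depth of each library. Read counts recovered from the deposited RPKM were whole within 0.01 for 28488 of 28488 genes. The library size in the RPKM denominator ranged from 28941934 to 35175186 per library. The tested genes had a median of 755 reads per library, and the lowest total over the 8 libraries was 7 reads. The length by which the authors divided was compared with a reference annotation of another build (GENCODE v29 on GRCh38), used only for lengths and GC content. It lay within 1 base of the mean length of the annotated transcripts for 47.1% of 12616 matched genes, against 11.8% for the median and 7.7% for the longest transcript. A mean over transcripts changes RPKM levels between genes but cancels in a fold change of 1 gene. GC content was available for 12616 tested genes, 97.4% of them.

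RPKM values are not counts, so no count model was the main test. Values were taken as log2(RPKM + 0.5), and genes with RPKM of at least 1 in at least 2 libraries were kept, which left 12958 of 28488 genes (45.5%), 11587 of them protein-coding. A fold change on this scale understates the change of low genes. All 8 libraries entered 1 limma fit with a mean per group, 4 residual degrees of freedom and a shared estimate of the spread (trended eBayes, 3.69 prior degrees of freedom). The 6 pairwise comparisons of the 4 groups were tested two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. R 4.3.3 with limma 3.58.1 was used for the tests, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for the tables and plots. Symbols shared by several entries were kept apart by their identifiers.

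The groups, the tests, 29 gene lists, the rule for named genes and 21 alternative settings were fixed before the data were examined. Lists with at least 3 tested members, 27 of the 29, were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists within a comparison. Camera asks whether a list ranks above or below all other genes, so its direction can differ from the sign of the list's median. Each list was tested again with an estimated correlation and with fry, which asks whether its genes move on balance one way and does not compare them with other genes. As a reference for noise, 12 values per list or trend were built from half-differences between libraries of the same group, each the sum or difference of those of 2 groups. Where differences within groups are said below to reach a value, it is the largest of these 12. The 2 libraries of a single group can lie further apart than that. Named genes were EZH2, then the 8 largest rises and 8 largest falls past the threshold in each comparison with the vector and the 5 largest of each between EZH2 forms, if the 2 libraries of a group both lay on the same side of the other group. For each list past the threshold, up to 4 members with the smallest p were added. Where fewer than 3 genes passed in a direction, the 5 with the smallest p were given as not passing. Clone, small RNA, antisense and pseudogene style names were counted but not named; MTND6P4 and MTATP8P1, copies of mitochondrial genes, were not caught by that rule.

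The tests were run first on simulated data built from the means of these libraries with known changes. Against the vector, the simulation of wild-type EZH2 on 12864 genes recovered 28.6% of 1.25-fold, 68.0% of 1.5-fold, 87.8% of 2-fold and 100% of 4-fold changes, with 5 false calls. The simulation of T372A on 12854 genes recovered 40.0%, 75.5%, 94.0% and 100%, with 10 false calls. The simulation of T372E on 12865 genes recovered 18.0%, 66.0%, 98.0% and 98.0%, with 12 false calls. In 20 simulated runs of the T372A comparison over 29 unchanged lists, camera made 1 false call, and a list of 30 genes shifted by 0.2 on the log2 scale was found in 20 of 20 runs. The simulated noise was independent between genes, had no trend with GC content or length and was equal in all groups. These runs therefore do not show how often camera makes false calls on lists of correlated genes.

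Alternatives included the pseudocount (0.1 and 1), no filter on level or a filter at RPKM 5, median centring, quantile normalization, eBayes without a trend or robust, library weights, a fit of only the groups compared, a block for the libraries numbered 1 to 4 against 5 to 8, other thresholds and leaving out each library in turn. A further 6 alternatives were added after the data were seen: voom on the recovered reads, scaling to the reads in listed genes, removal of each library's trend with either of 2 gene lengths or with GC content, and a fit of the 6 EZH2 libraries alone. Where a library was left out, its group kept 1 library, which was assumed to vary like the other groups. The 3 comparisons with the vector share the same 2 vector libraries, so correlations between their changes were set beside 12 sets of simulated unchanged groups.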

Results

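Messenger RNA levels were measured by RNA sequencing in TOV112D cells, an established human ovarian endometrioid carcinoma line, 72 h after transient transfection. The 8 libraries fell into 4 groups of 2: an empty vector, wild-type EZH2, T372A EZH2 and T372E EZH2. EZH2 is the catalytic subunit of Polycomb repressive complex PRC2, which places a silencing methyl mark on histones. T372A replaces a threonine by alanine, which cannot be phosphorylated, and T372E replaces it by glutamate, which is often used to mimic a phosphate. From the series title, the work concerns phosphorylation of EZH2 by protein kinase A and its bearing on STAT3 and on the oncogenic role of EZH2. Depth was similar across libraries, with library sizes of 28941934 to 35175186 reads in the RPKM denominator, of which 80.7% to 83.9% were recovered in listed genes. Between 12589 and 12731 genes reached 1 RPKM in a library.

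The 2 libraries of a group correlated across genes with r = 0.9928 for the vector and 0.9972, 0.9975 and 0.9973 for wild-type, T372A and T372E EZH2, while libraries of different groups correlated with r = 0.9916 to 0.9973. Genes are not independent replicates, so these are descriptions of the libraries. The vector pair stood apart: the SD of its log2 difference was 0.25, against 0.15, 0.14 and 0.15 in the other groups. Its libraries deviated in opposite directions with GC content, by -0.31 in vector replicate 1 and 0.28 in vector replicate 2 on the log2 scale from the lowest to the highest decile of genes. Because the 4 groups shared 1 estimate of the spread, this pair widened the error of every comparison, including those between EZH2 forms. A fit of the 6 EZH2 libraries alone, chosen after the data were seen, is given beside each of those. Leaving out the pair with the largest spread after seeing it can make p-values too small and counts too large.

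**Figure D1:**
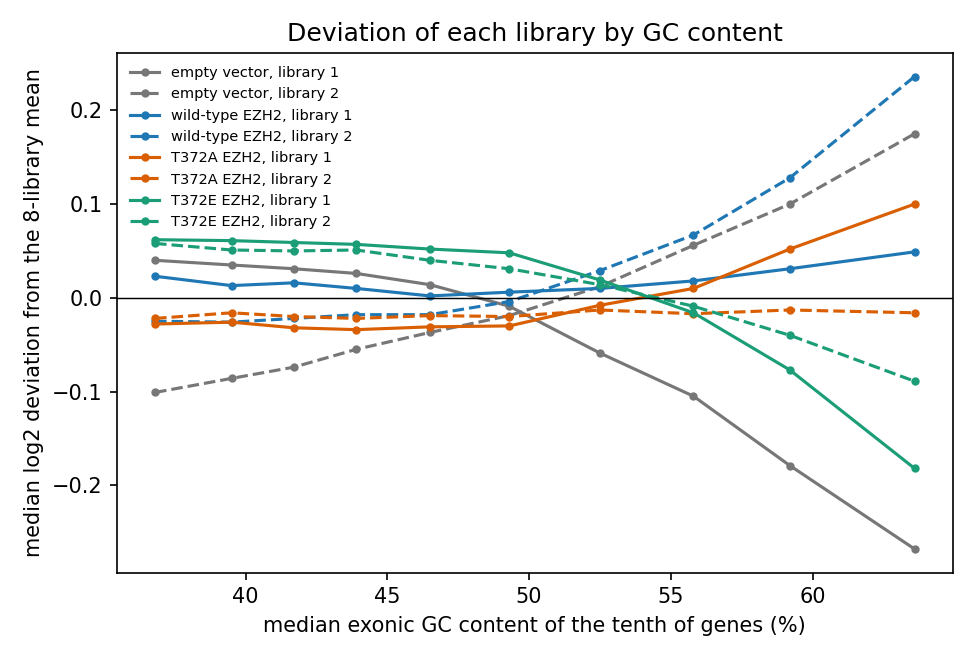
Median log2 deviation of each library from the mean of the 8 libraries, plotted against the median exonic GC content (%) of 10 equal groups of tested genes; solid and dashed lines are the 2 libraries of a group. From the lowest to the highest decile, vector replicate 1 moved by -0.31 and vector replicate 2 by 0.28.

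EZH2 transcripts rose far above the vector level with each construct. EZH2 (ENSG00000106462.6, minus strand of chromosome 7, 148504475 to 148581413 on hg19) stood at 27.3 ± 1.47 RPKM (SD, n = 2) with the vector. It reached 777 ± 16.1 RPKM (n = 2) with wild-type EZH2, 658 ± 5.39 (n = 2) with T372A and 653 ± 1.05 (n = 2) with T372E, or 28.4, 24.1 and 23.9 times the vector mean. On the log2(RPKM + 0.5) scale the rises were 4.81, 4.57 and 4.55 (SE 0.04 each; limma adjusted p = 1.3e-09, 1.9e-09 and 2e-09). Both mutants lay slightly below wild-type EZH2, by -0.24 for T372A (adjusted p = 0.17) and -0.25 for T372E (adjusted p = 0.3), differences that did not pass. T372A and T372E EZH2 differed by -0.01 (adjusted p = 0.9). The recovered reads ran from 1759 to 61149 per library, so counting error was small.

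**Figure D2:**
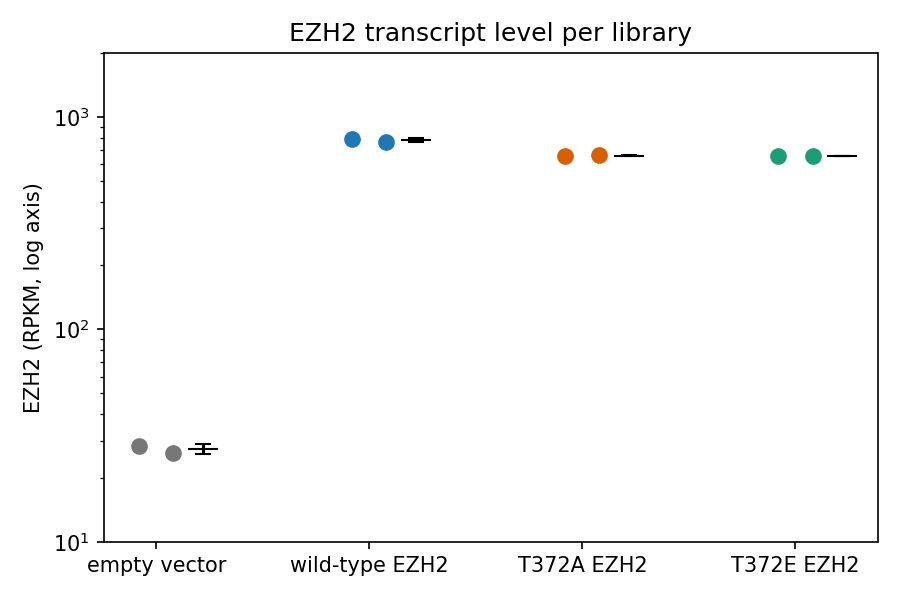
EZH2 level in RPKM on a log axis for each of the 8 libraries (points), with the group mean and SD (bars, n = 2). The vector libraries lie at 26.3 and 28.4 RPKM and the 6 EZH2 libraries between 652 and 788.4 RPKM.

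The comparison of wild-type EZH2 with the vector asks what raising EZH2 does to the other transcripts of these cells. EZH2 was the only gene past the threshold. The median fold of all tested genes was 0.042, a shift that the list medians and sign counts below include. Transcripts of the mitochondrial genome, which encode respiratory chain subunits, were lower as a group: 13 of 13 folds were negative with a median of -0.18 on the log2 scale (camera adjusted p = 1.1e-19, but adjusted p = 0.25 with an estimated correlation and 0.072 by fry). Examples were MT-ATP6 (824 ± 5.37 against 953 ± 32.2 RPKM; -0.21, SE 0.04, adjusted p = 0.48) and MT-CYB (-0.22, adjusted p = 0.49). Interferon-stimulated genes were higher, with 23 of 26 positive folds and a median of 0.08 (camera adjusted p = 0.0056, adjusted p = 0.25 with an estimated correlation). They were led by the antiviral gene IFIT1 (5.12 ± 0.0912 against 3.64 ± 0.154 RPKM, n = 2 each, log2 fold 0.44, SE 0.08, limma adjusted p = 0.48) and IRF9, an interferon regulatory factor (0.33). The IFIT1 relatives IFIT3 (1.42 ± 0.134 against 0.799 ± 0.057 RPKM, log2 fold 0.56) and IFIT2 (1.15 ± 0.0644 against 0.629 ± 0.0209 RPKM, log2 fold 0.55) lay near the filter of 1 RPKM. Hypoxia and glycolysis genes were higher (17 of 20 positive, median 0.11, camera adjusted p = 0.031, adjusted p = 0.25 with an estimated correlation). Among them were PDK1, a kinase that inhibits pyruvate dehydrogenase (5.59 ± 0.269 against 4.35 ± 0.202 RPKM, log2 fold 0.33), BNIP3L (0.17) and P4HA2 (0.14). Genes of the G1/S transition and DNA replication were lower (20 of 28 negative, median -0.03, camera adjusted p = 0.0022, adjusted p = 0.25 with an estimated correlation), such as GINS2 (-0.17), RRM2 (-0.11) and the replication clamp PCNA (221 ± 0.551 against 235 ± 0.394 RPKM; -0.08).

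Over all genes 0 members of these 4 lists passed limma for wild-type EZH2 against the vector; adjusted over the list alone, 12 mitochondrial genes fell, 4 interferon and 1 hypoxia gene rose, and 0 G1/S genes passed. Beside the mitochondrial list, the share of the RPKM denominator outside listed genes was 17.4% ± 0.01 (SD, n = 2) with wild-type EZH2 and 18.7% ± 0.22 (n = 2) with the vector. At an unadjusted p under 0.05 there were 1136 genes (8.8%), against 648 by chance, and voom also called 1. Genes with the smallest p that did not pass were DYNC1H1, the dynein heavy chain (0.34), TRIM44 (0.35), SMCR8 (0.48), ZBED6 (0.62) and ZDHHC20 (0.39), each at adjusted p = 0.37. On the lower side they were MTND6P4 (-0.60), MTATP8P1 (-0.35) and SNRPF (-0.20). Without vector replicate 2 the count was 2213 and the interferon, G1/S and hypoxia calls were lost (adjusted p = 0.44, 0.18 and 0.18); the hypoxia call was also lost without either wild-type library (0.054 and 0.093). With the GC trend removed 90 genes passed, and the hypoxia list missed the threshold after median centring (0.22).

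The comparison of T372A EZH2 with the vector addresses the form that cannot be phosphorylated at this site. Mitochondrial transcripts rose: 8 transcripts of the mitochondrial genome passed, 6 of them among the 13 listed protein-coding genes. MT-ND6, a subunit of respiratory complex I (ENSG00000198695.2, mitochondrial genome, 14149 to 14673), rose from 55.7 ± 5.46 to 93.1 ± 4.82 RPKM (n = 2 each; log2 0.74, SE 0.08, limma adjusted p = 0.028). MT-ND2 (0.44), MT-ND1 (0.39), MT-ATP6 (0.38), MT-ND4 (0.34) and MT-ND5 (0.32) rose as well, as did the ribosomal RNAs MT-RNR2, from 2440 ± 89.8 to 3230 ± 136 RPKM (0.40), and MT-RNR1 (0.30). Ribosomal protein transcripts fell in 2 cases, RPL27 (ENSG00000131469.8, chromosome 17, 41150290 to 41154976) from 1450 ± 31.5 to 1200 ± 12.3 RPKM (-0.27, SE 0.03, adjusted p = 0.035) and RPS18 (ENSG00000231500.2, chromosome 6, 33239787 to 33244287) from 4020 ± 22.2 to 3450 ± 43.9 RPKM (-0.22, adjusted p = 0.039). RPS14 (-0.23, adjusted p = 0.052) and RPS3 (-0.20, adjusted p = 0.064) lay lower without passing, as did RGCC (-0.30), CMC2 (-0.26) and the ATP synthase subunit ATP5O (-0.26).

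As groups, the mitochondrial list lay higher in the T372A libraries than in the vector libraries (13 of 13 positive, median 0.35, camera adjusted p = 7.1e-24) and the ribosomal protein list lower (31 of 32 negative, median -0.13, camera adjusted p = 7.4e-17). Both had adjusted p = 0.14 with an estimated correlation, and fry gave 0.051 for the ribosomal protein list. Hypoxia and glycolysis genes were higher (17 of 20 positive, median 0.12, camera adjusted p = 2.4e-05, adjusted p = 0.14 with an estimated correlation). PDK1 (ENSG00000152256.9) stood at 6.78 ± 0.0962 against 4.35 ± 0.202 RPKM (0.59, adjusted p = 0.052), and the glycolytic enzymes HK2 (0.25) and ENO2 (0.22) and BNIP3 (0.22) were also on the higher side. Cholesterol synthesis genes were lower (16 of 22 negative, median -0.07, camera adjusted p = 0.00044, adjusted p = 0.14 with an estimated correlation). Examples were FDPS, an enzyme of the mevalonate pathway (263 ± 1.02 against 310 ± 6.13 RPKM; -0.23), MSMO1 (-0.20), ACAT2 (-0.14) and FDFT1 (-0.13). Over all genes, 0 hypoxia and 0 cholesterol genes passed; adjusted over the list alone, 13 mitochondrial and 4 hypoxia genes rose and 17 ribosomal protein genes and 1 cholesterol gene fell. The share of reads outside listed genes was 19.2% ± 0.11 (n = 2) against 18.7% ± 0.22, and the longest decile of genes lay 0.17 above the shortest on the log2 scale, where differences within groups reached 0.07; these stand beside the mitochondrial and ribosomal protein groups.

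In all, 11 genes passed for T372A against the vector, 9 rising, EZH2 among them, and 2 falling. At an unadjusted p under 0.05 there were 1715 genes, and voom called 34, 24 rising and 10 falling. Median centring or removing either length trend left 1 rise, EZH2, and 0 falls, and without a level filter 8 genes passed, 1 of the 11 among them. With the trend with the length in the values or the longest transcript removed, the 8 other rises had a median of 105% and 112% of their log2 fold before and the 2 falls 81.4% and 84.2%, while SEs were larger (median ratios 1.45 and 1.53, and 1.75 and 1.78). The count was 1, EZH2, when any single one of the 6 EZH2 libraries was left out, 281 without vector replicate 1, 1892 without vector replicate 2 and 952 with the GC trend removed.

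The comparison of T372E EZH2 with the vector addresses the form that mimics phosphorylation. EZH2 was again the only gene past the threshold. All tested genes had a median fold of 0.046, a shift that the list medians and sign counts below include. Mitochondrial transcripts were lower as a group (13 of 13 negative, median -0.28, camera adjusted p = 2e-40, adjusted p = 0.19 with an estimated correlation). Examples were MT-ATP6 (784 ± 4.39 against 953 ± 32.2 RPKM, n = 2 each; -0.28, SE 0.04, limma adjusted p = 0.3), MT-ND2 (-0.32), MT-ND1 (-0.27) and MT-RNR2 (-0.26). Genes of the unfolded protein and amino acid stress response were higher (20 of 23 positive, median 0.07, camera adjusted p = 0.034, adjusted p = 0.24 with an estimated correlation). They were led by DDIT3, the transcription factor also called CHOP (ENSG00000175197.6, chromosome 12, 57910371 to 57914300), at 64.8 ± 3.92 against 49.6 ± 0.854 RPKM (0.38, SE 0.05, limma adjusted p = 0.3), with HERPUD1 (0.25), TRIB3 (0.22) and the chaperone HSPA5 (0.11). Heat shock genes were higher (11 of 13 positive, median 0.10, camera adjusted p = 0.01, adjusted p = 0.19 with an estimated correlation), as HSPH1 (0.16), CHORDC1 (0.13) and HSP90AB1 (0.10). Hypoxia and glycolysis genes were higher too (17 of 20 positive, median 0.10, camera adjusted p = 0.01, adjusted p = 0.19 with an estimated correlation), as PDK1 (0.37), BNIP3 (0.20) and ENO2 (0.17). G1/S genes ranked lower in the test (camera adjusted p = 0.01, adjusted p = 0.19 with an estimated correlation, fry 0.053) with a mean of -0.02 and a median of 0.01. Median and test thus differed in sign, and the median lay within the 0.03 reached by differences within groups. E2F1 (-0.18) and CDC45 (-0.17) were on the lower side and DTL (0.10) on the higher.

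Over all genes 0 members passed limma in the T372E comparison; adjusted over the list alone, 13 mitochondrial genes fell, 3 stress response genes and 1 hypoxia gene rose, and 0 heat shock and 0 G1/S genes passed. The share of reads outside listed genes was 16.2% ± 0.12 (n = 2) with T372E against 18.7% ± 0.22 with the vector. At an unadjusted p under 0.05 there were 1074 genes, and voom called 10, 1 rising and 9 falling; quantile normalization gave 1 rising and 4 falling, against 1 and 0. Others with the smallest p that did not pass were the stress-induced factor ATF3 (0.56), PABPC1 (0.16) and PTGS2 (0.45). Without vector replicate 1 the count was 1463 and the stress, heat shock, G1/S and hypoxia calls were lost (0.39, 0.11, 0.33 and 0.33), while without vector replicate 2 the count was 2. The stress call was also lost without wild-type replicate 1 (0.052) or 2 (0.051) or T372E replicate 1 (0.21), and the heat shock and G1/S calls without T372E replicate 2 (0.055 each).

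**Figure D3:**
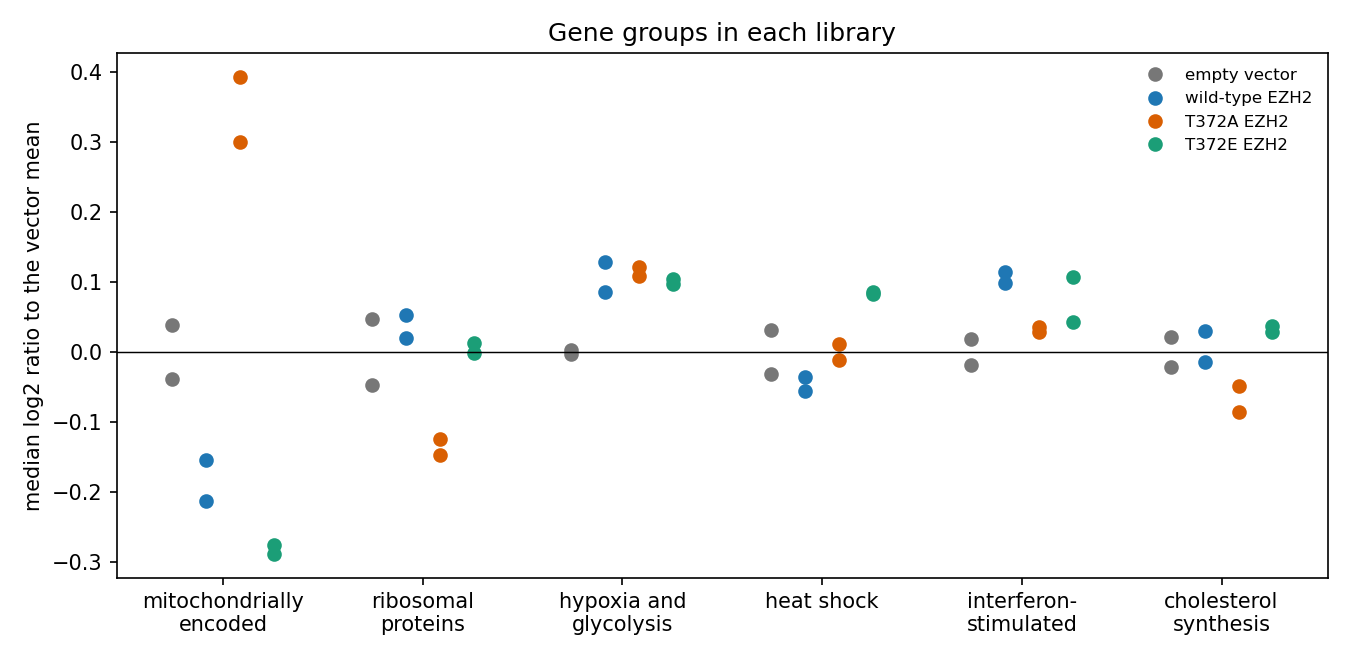
Median log2 ratio to the mean of the vector libraries for 6 gene lists (horizontal axis), with 1 point per library and colours for the 4 groups. The T372A libraries lie highest for mitochondrially encoded genes and lowest for ribosomal proteins, and the T372E libraries lowest for mitochondrially encoded genes; in the camera test the medians against the vector were 0.35, -0.13 and -0.28.

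The comparison of T372A with wild-type EZH2 asks what losing the phosphorylation site changes; EZH2 itself stood at 658 ± 5.39 with T372A against 777 ± 16.1 RPKM (-0.24, limma adjusted p = 0.17). Mitochondrial transcripts rose with T372A: 14 transcripts of the mitochondrial genome passed, 12 of the 13 listed genes among them. MT-ND6 was 93.1 ± 4.82 against 43.0 ± 2.47 RPKM (n = 2 each; 1.11, SE 0.08, limma adjusted p = 0.0021), MT-ND2 676 ± 26.8 against 428 ± 8.39 RPKM (0.66) and MT-ATP6 1240 ± 51.1 against 824 ± 5.37 RPKM (0.59). MTND6P4 (1.18) and MTATP8P1 (0.73), nuclear copies that share reads with the mitochondrial genes, rose too and are uncertain for that reason. Ribosomal protein transcripts fell in 3 cases, RPS14 (506 ± 2.43 against 596 ± 7.03 RPKM; -0.24, adjusted p = 0.029), RPL27 (-0.23) and RPS18 (-0.22), and so did SNRPD2, a core spliceosomal protein (353 ± 1.18 against 421 ± 6.38 RPKM; -0.25, adjusted p = 0.027).

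Between T372A and wild-type EZH2, 9 lists passed camera. All tested genes had a median fold of -0.034, which the list medians and sign counts include. The mitochondrial list lay higher (13 of 13 positive, median 0.51, adjusted p = 1.6e-53) and the ribosomal proteins lower (32 of 32 negative, median -0.18, 2.5e-23), both with adjusted p = 0.12 with an estimated correlation. Cholesterol synthesis genes were lower (21 of 22 negative, median -0.09, camera adjusted p = 0.008, adjusted p = 0.18 with an estimated correlation), as EBP (-0.17) and NSDHL (-0.15). Interferon-stimulated genes were lower (20 of 26 negative, median -0.08, camera adjusted p = 0.047, adjusted p = 0.21 with an estimated correlation). IFIT1 stood at 3.32 ± 0.0418 against 5.12 ± 0.0912 RPKM (-0.56, limma adjusted p = 0.063) and IFI6 differed by -0.29. The 4 tested epithelial genes ranked higher (4 of 4 positive, median 0.09, camera adjusted p = 0.013, adjusted p = 0.28 with an estimated correlation, fry 0.23), as MUC1 (0.43) and EPCAM (0.13). The other 4 lists past the camera threshold had medians within the largest difference within groups. These were PRC2 subunits other than EZH2 (0.04 within 0.05; EZH1 0.17, AEBP2 0.11), heat shock genes (0.02 within 0.04; DNAJA1 0.13), hypoxia and glycolysis genes (0.01 within 0.04; SLC2A3 0.18, PDK1 0.26) and TGF-beta targets (0.03 within 0.11; ID2 0.12). They ranked higher, with 10 of 12, 8 of 13, 11 of 20 and 12 of 17 positive folds, at camera adjusted p = 0.012, 0.033, 0.012 and 0.012. Their adjusted p was 0.21, 0.21, 0.18 and 0.28 with an estimated correlation and 0.19, 0.19, 0.055 and 0.65 by fry. Adjusted over the list alone, 13 mitochondrial genes rose, 23 ribosomal protein genes and 1 interferon gene fell, and 0 genes of the other 6 lists passed by either adjustment. The share of reads outside listed genes was 19.2% ± 0.11 with T372A and 17.4% ± 0.01 with wild-type EZH2 (n = 2 each). The longest decile of genes lay 0.10 above the shortest on the log2 scale, where the largest of the 12 values built from half-differences within groups was 0.07. Single libraries stood at 0.085 and 0.101 with T372A, 0.008 and -0.032 with wild-type EZH2 and -0.027 and -0.126 with the vector.

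In all, 23 genes passed for T372A against wild-type EZH2, 18 rising and 5 falling, with 1092 at an unadjusted p under 0.05 and 21 by voom. The split was 19 to 0 after median centring, 19 to 1 after scaling to the reads in listed genes and 18 to 0 with either length trend removed, where the 5 falls did not pass. They had a median of 66.1% and 68.2% of their log2 fold before, with SEs a median of 1.54 times as large: RPS14 stood at -0.18 and -0.20 (-0.24 before), RPL27 at -0.15 and -0.16 (-0.23), RPS18 at -0.14 and -0.13 (-0.22) and SNRPD2 at -0.17 and -0.16 (-0.25). Leaving out any single EZH2 library also left 0 falls, and without a level filter 17 genes passed, 8 of the 23 among them. The count was 7 and 8 without wild-type replicates 1 and 2, 13 and 7 without T372A replicates 1 and 2, 15 without either T372E library, 260 and 272 without vector replicates 1 and 2, and 263 (48 rising, 215 falling) with the 6 EZH2 libraries alone. Without wild-type replicate 1 the calls of the PRC2, interferon, heat shock, epithelial, cholesterol, hypoxia and TGF-beta lists were lost (adjusted p = 0.06, 0.12, 0.091, 0.06, 0.06, 0.081 and 0.17). The PRC2, interferon and TGF-beta calls were also lost without T372A replicate 1 (0.054, 0.12 and 0.16), the heat shock call without wild-type replicate 2 (0.065) or T372A replicate 2 (0.19), and the interferon call without either vector library (0.11 each) and in the 6 EZH2 libraries (0.11).

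The comparison of T372E with wild-type EZH2 sets the phosphate mimic against the form that can be phosphorylated. Heat shock genes were higher with T372E (10 of 13 positive, median 0.13, camera adjusted p = 0.0015, adjusted p = 0.41 with an estimated correlation). Examples were the chaperones and co-chaperones DNAJA1 (412 ± 0.327 against 359 ± 0.94 RPKM, n = 2 each; 0.20, SE 0.04, limma adjusted p = 0.3), CHORDC1 (0.24), HSPE1 (0.20) and HSP90AB1 (0.14). PRC2 subunits other than EZH2 were higher (10 of 12 positive, median 0.09, camera adjusted p = 0.032, adjusted p = 0.49 with an estimated correlation, fry 0.053). Examples were EZH1, the paralog of EZH2 (11.1 ± 0.179 against 9.32 ± 0.843 RPKM; 0.24), C17orf96 (0.17), AEBP2 (0.15) and RBBP7 (0.14). Mitochondrial transcripts were lower (12 of 13 negative, median -0.11, camera adjusted p = 5.1e-05, adjusted p = 0.86 with an estimated correlation, fry 0.28), as MT-ND4L (-0.22) and MT-ND3 (-0.20). Over all genes 0 passed in limma, 0 in voom and 1997 had an unadjusted p under 0.05, and adjusted over the list alone 7 heat shock and 3 PRC2 genes rose and 1 mitochondrial gene fell. The smallest p belonged to USMG5, an ATP synthase subunit (ENSG00000173915.8, chromosome 10, 105148798 to 105156223), at 167 ± 1.88 against 119 ± 4.24 RPKM (0.48), CCDC84 (0.49), EIF4A2 (0.28), ANP32B (0.20) and C1orf63 (0.35) on the higher side, each at limma adjusted p = 0.3. On the lower side it belonged to DYNC1H1 (-0.32), RNF213 (-0.30), EZH2 (-0.25), PSMA7 (-0.20) and NCK2 (-0.31), again at limma adjusted p = 0.3.

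The share of reads outside listed genes was 16.2% ± 0.12 with T372E and 17.4% ± 0.01 with wild-type EZH2 (n = 2 each). Genes of the highest GC decile lay at -0.34 relative to the lowest, where differences within groups reached 0.40. That 0.40 comes from values built with the vector pair (-0.309 and 0.276), which is not in this comparison. Single libraries stood at -0.244 and -0.147 with T372E and at 0.026 and 0.262 with wild-type EZH2, so each T372E library lay below each wild-type library. The count was 1515 and 1563 without vector replicates 1 and 2, and 1554 with the 6 EZH2 libraries alone, 703 rising and 851 falling. The PRC2 call was lost without vector replicate 1 (0.05), wild-type replicate 1 (0.15) or T372E replicate 2 (0.068), after median centring (0.052) and with either length trend removed (0.051 and 0.11), and the mitochondrial call when the trend with the longest transcript was removed (0.088).

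The comparison of T372E with T372A EZH2 sets both substitutions against each other. Mitochondrial transcripts were lower with T372E: 15 transcripts of the mitochondrial genome fell, including 13 of the 13 listed genes. MT-ND6 fell from 93.1 ± 4.82 to 43.9 ± 1.82 RPKM (n = 2 each; -1.08, SE 0.08, limma adjusted p = 0.0014), MT-ND2 from 676 ± 26.8 to 397 ± 12.8 RPKM (-0.76, adjusted p = 0.00065), MT-ATP8 by -0.76, MT-ND3 by -0.68 and MT-ND1 by -0.66; the copy MTND6P4 (-0.84) is uncertain. Ribosomal protein transcripts rose in 15 cases, among them RPS15A (350 ± 0.718 to 460 ± 12 RPKM; 0.39, adjusted p = 0.027), RPL27 (1200 ± 12.3 to 1490 ± 16.7 RPKM; 0.31, adjusted p = 0.0077), RPS12 (0.30), RPS18 (0.24) and RPS14 (0.24). USMG5 rose from 118 ± 5.48 to 167 ± 1.88 RPKM (0.50, SE 0.06, adjusted p = 0.027), and so did MED31, a Mediator subunit (16.9 ± 0.397 to 23.0 ± 0.234 RPKM; 0.43), SNRPG, a spliceosomal Sm protein (0.39), and EBPL (0.38).

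**Figure D4:**
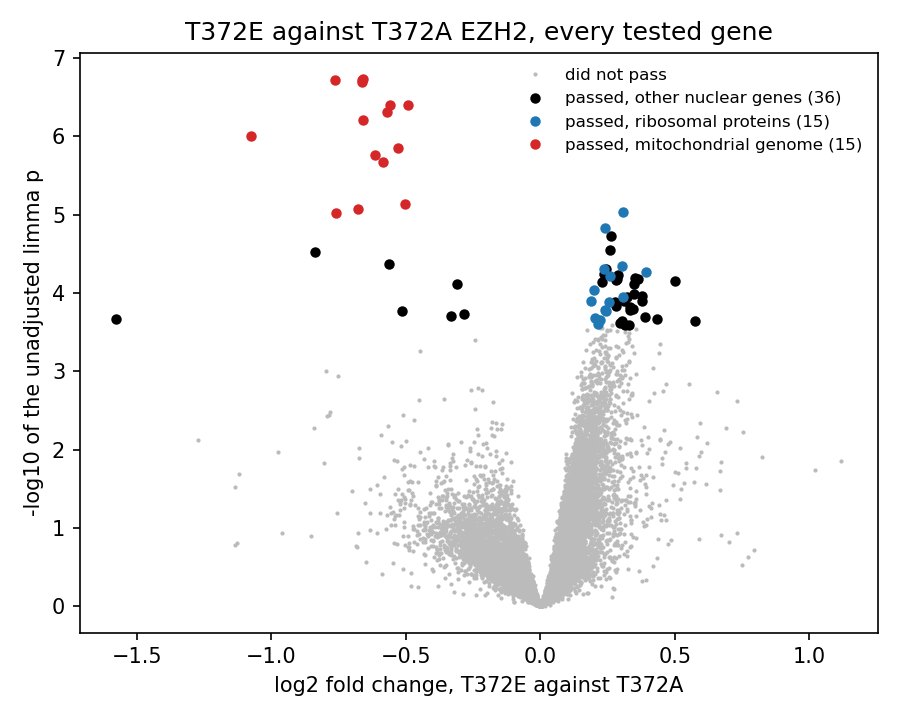
Log2 fold change of T372E against T372A EZH2 (horizontal) and -log10 of the unadjusted limma p (vertical) for 12958 tested genes, each a point. The 66 genes past the threshold comprise 15 transcripts of the mitochondrial genome on the lower side, 15 ribosomal protein genes on the higher side and 36 other nuclear genes; after median centring 0 genes remained on the higher side.

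As groups, mitochondrial genes lay lower (13 of 13 negative, median -0.66, camera adjusted p = 1.5e-39) and ribosomal proteins higher (25 of 32 positive, median 0.15, 1.5e-08) with T372E than with T372A. Their adjusted p was 0.24 and 0.34 with an estimated correlation, and fry gave 0.065 for the ribosomal proteins. All tested genes had a median fold of 0.035, which the list medians and sign counts include. Cholesterol synthesis genes were higher (17 of 22 positive, median 0.10, camera adjusted p = 0.016, adjusted p = 0.34 with an estimated correlation), as MSMO1 (45.7 ± 0.206 to 56.0 ± 1.61 RPKM; 0.29, limma adjusted p = 0.11), FDPS (0.19) and ACAT2 (0.17). TGF-beta targets ranked lower (12 of 17 negative, camera adjusted p = 0.016, adjusted p = 0.44 with an estimated correlation, fry 0.41), but their median of -0.06 lay within the 0.11 reached by differences within groups; TAGLN (-0.40), ID3 (-0.35) and JUNB (-0.45) were among them. Of the listed ribosomal protein genes 8 rose over all genes and 18 adjusted over the list alone; adjusted that way, 13 mitochondrial genes fell and 8 cholesterol genes rose, and 0 TGF-beta targets passed. The G2/M and mitosis list did not pass (21 of 29 positive, median 0.08, 0.3); 1 member rose over all genes, CKS2, which binds cyclin-dependent kinases (0.29; chosen after its value was seen), and 4 rose and 2 fell adjusted over the list alone (14 calls over the 6 comparisons). The share of reads outside listed genes was 16.2% ± 0.12 with T372E and 19.2% ± 0.11 with T372A (n = 2 each), and 31 of the 44 nuclear genes that rose had a longest transcript under 2177 bases, where the median of tested genes was 3492 bases.

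In all, 66 genes passed for T372E against T372A, 44 rising and 22 falling, with 2181 at an unadjusted p under 0.05 and 30 by voom (8 rising, 22 falling). The split was 0 to 18 after median centring, 9 to 21 after quantile normalization and 3 to 22 after scaling to the reads in listed genes. It was 0 to 18 and 1 to 18 with the trend with the length in the values or the longest transcript removed. The 44 and 43 rises that did not pass there had a median of 85.3% and 88.5% of their log2 fold before, with SEs a median of 1.42 and 1.39 times as large. USMG5 stood at 0.46 with either removed (0.50 before), MED31 at 0.39 (0.43) and RPL27 at 0.26 and 0.27 (0.31). Leaving out any single T372A or T372E library left 0 rises and leaving out either wild-type library left 1. The count was 18 without either wild-type library, 13 and 12 without T372A replicates 1 and 2, 12 and 13 without T372E replicates 1 and 2, 1574 and 1618 without vector replicates 1 and 2, and 1584 (1333 rising, 251 falling) with the 6 EZH2 libraries alone. The cholesterol call was lost without T372A replicate 2 (0.077) or T372E replicate 2 (0.069) and after quantile normalization (0.29), and the TGF-beta call without T372A replicate 1 (0.066) or T372E replicate 1 (0.061) and with the GC trend removed (0.12).

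Of the lists closest to the title, PRC2 subunits other than EZH2 passed camera for T372A and T372E against wild-type EZH2 (adjusted p = 0.012 and 0.032, and adjusted p = 0.21 and 0.49 with an estimated correlation). The STAT3 targets, JAK-STAT components, PKA subunits and anchoring proteins, cAMP and CREB targets, PRC2-silenced genes and PRC1 subunits passed in none of the 6 comparisons. STAT3 itself (ENSG00000168610.10, chromosome 17, 40465342 to 40540586) stood at 37.0 ± 0.397 RPKM with the vector, 37.0 ± 0.165 with wild-type EZH2, 37.5 ± 0.103 with T372A and 37.4 ± 0.705 with T372E (n = 2 each; limma adjusted p = 0.998, 0.875 and 0.909 against the vector); it was chosen for the title, after its values were seen. The 24 tested STAT3 targets had medians between -0.03 and 0.05 over the 6 comparisons, with no camera adjusted p below 0.33, and 1 gene passed adjusted over the list alone. Components of the JAK-STAT pathway (19 tested) had medians between 0.00 and 0.08 and PKA subunits and anchoring proteins (19 tested) between 0.01 and 0.09, with lowest camera adjusted p of 0.33 and 0.074. Adjusted over the list alone, 0 JAK-STAT genes and 1 PKA gene passed. In T372E against the vector, fry gave adjusted p = 0.024 for the JAK-STAT list, 0.036 for the PKA list and 0.036 for PRC2 subunits other than EZH2. Their medians were 0.08, 0.09 and 0.07 where that of all tested genes was 0.046, a shift that fry does not take off. The PRC2 list had no camera call there (adjusted p = 0.22). The cAMP and CREB targets (13 tested) had medians between -0.03 and 0.08 and no camera call (0.54 at lowest), with 2 genes passing adjusted over the list alone. Genes known as PRC2-silenced had medians between -0.01 and 0.04 (21 tested, camera adjusted p = 0.37 at lowest), with 2 gene calls adjusted over the list alone, and 18 of the 39 in the table (46.2%) lay under the level filter. PRC1 subunits (20 tested) had medians between -0.02 and 0.06 and no camera call (0.41 at lowest), with 1 gene call adjusted over the list alone.

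No camera call was made in any of the 6 comparisons for immediate early genes (18 tested, medians 0.01 to 0.08, lowest adjusted p 0.074), NF-kB and inflammatory targets (9 tested, -0.01 to 0.09, 0.31), p53 targets (16 tested, -0.05 to 0.07, 0.73), mesenchymal genes (18 tested, -0.02 to 0.07, 0.28) and stem cell genes (9 tested, -0.01 to 0.07, 0.64). The same held for MHC class I antigen presentation (15 tested, -0.09 to 0.07, 0.13) and replication-dependent histone genes (7 tested, -0.10 to 0.10, 0.14). Among markers of other cell types, 9 of the 9 endothelial genes in the table lay under the level filter (ESAM highest, 0.306 RPKM), and 2 of 10 blood cell genes were tested (CD68 highest, 20.1 RPKM), too few for a test. Fibroblast markers (10 tested) had medians between -0.05 and 0.07 (0.59 at lowest), with COL3A1 at 2720 RPKM, and neuronal markers (5 tested) between -0.03 and 0.10 (0.6 at lowest), with STMN2 highest at 6.29 RPKM. In limma over all genes 0 members of these lists passed. Adjusted over the list alone, the calls over the 6 comparisons numbered 1 for immediate early genes, 1 for NF-kB targets, 3 for mesenchymal genes, 4 for MHC class I genes, 1 for fibroblast markers and 0 for p53, stem cell, histone and neuronal genes. The lowest fry adjusted p was 0.04 for NF-kB targets and 0.016 for histone genes.

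The changes of the 3 EZH2 forms against the shared vector libraries were compared across 12957 genes, leaving out EZH2. The correlation was r = 0.57 between wild-type and T372A EZH2 (Spearman 0.60), 0.12 between wild-type and T372E (0.07) and 0.29 between T372A and T372E (0.24), where simulated unchanged groups against the same vector libraries gave 0.74 on average (0.68 to 0.84 in 12 sets). The covariances were 0.0108, 0.00212 and 0.00477, below the simulated mean of 0.0154 by -0.0046, -0.0133 and -0.0106. EZH2, the transfected gene, was the 1 gene called in both lists of each pair, and no other gene was shared. Independent lists would share 0.000695, 7.72e-05 and 0.000695 rising genes. As the EZH2 call followed from the transfection, this overlap does not test for shared changes. All 3 correlations lay below those of the 12 simulated sets. Those sets took the vector error from the difference within the vector pair, which holds its opposite GC trends (-0.31 and 0.28) in full. In the vector mean, which the observed changes used, such trends partly cancel. The simulated values may therefore be too high, and the comparison does not decide whether the 3 forms share changes. The controls were not split, since each part would hold 1 library. Without vector replicate 2 the correlations were 0.83, 0.62 and 0.64, without vector replicate 1 those with T372E were 0.54 and 0.67, and without wild-type replicate 1 that of wild-type with T372E was -0.04.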

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

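Of the tests in this part, the one of library-size scaling for mitochondrial transcripts was chosen after its result was seen.

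The share of the RPKM denominator outside the recovered reads of listed genes, also given above, was highest in the T372A libraries. Its mean was 19.18% there, 18.67% with the vector, 17.43% with wild-type EZH2 and 16.16% with T372E. The groups ranked in the same order by the median of the mitochondrial list against the vector (0.346 for T372A, -0.181 for wild-type EZH2, -0.282 for T372E). A link between the share and these medians was not tested. COL1A2, under the level filter, had 247 reads over the 6 EZH2 libraries and 59 over the 2 vector libraries, and each EZH2 library lay above both vector libraries in RPKM (ratio 1.33, 95% counting interval 1 to 1.8). HSPA6, a heat shock gene under the filter, had 123 reads against 5 (ratio 7.82, 3.26 to 24.5). LTBP2, also under the filter, had 348 reads against 78 (ratio 1.42, 1.11 to 1.8). These 3 were among 52 list members under the filter with at least 50 reads, 5.77%, close to the 5.02% (138 of 2750) of all genes under the filter, where chance gives 3.57% in each direction. In the other direction, 2 list members (3.85%) and 89 of all genes (3.24%) lay below both vector libraries in the 6 EZH2 libraries. The intervals cover counting error only.

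Mitochondrially encoded transcripts were higher with T372A than with the vector, by a median of 0.346 on the log2 scale over 13 genes. Median centring, which takes off any factor shared by all genes of a library, left a median of 0.32 where differences within groups reached 0.122, which argues against the library-size scaling as the whole cause. Removing each library's trend with the longest transcript left 0.396 and removing the GC trend left 0.35, where differences within groups reached 0.127 and 0.044, which argues against a length or a GC trend. With either length trend removed the single genes no longer passed, MT-ND6 with 0.80 (SE 0.090 and 0.095, limma adjusted p = 0.085 and 0.13) against 0.74 before (SE 0.077, 0.028), while the largest within-group value of the list went from 0.078 to 0.127. A difference in culture or RNA preparation, confounded with the construct, stays open beside the hypothesis that T372A EZH2 may raise these transcripts.

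Ribosomal protein transcripts were lower with T372A than with the vector, by a median of -0.129 over 32 genes. Removing the trend with the length in the values left -0.092 and removing the GC trend left -0.14, where differences within groups reached 0.029 and 0.036. A smooth length trend may thus account for part of the shift but left a remainder. These genes are also abundant, with a median of 998 RPKM, and no random lists matched on length and level were drawn for them. A shift of short and abundant transcripts therefore stays open. Without the length trend RPL27 (-0.22, SE 0.053, against -0.27, SE 0.030) and RPS18 (-0.17, SE 0.043, against -0.22, SE 0.025) no longer passed (limma adjusted p = 0.49 each). Against each vector library alone the median was -0.094 and -0.194, so that 1 vector library was not the source. A difference between cultures and an effect of T372A EZH2 both stay open and were not tested.

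In the comparisons of wild-type and T372E EZH2 with the vector, no gene other than EZH2 passed in limma, where 1136 and 1074 genes had an unadjusted p under 0.05 and voom called 1 and 10. A spread too large for 2-fold changes stays open: a simulation recovered 87.8% and 98% of them, but 8 and 10 genes other than EZH2 lay over 2-fold without passing, 0 and 1 of them at a mean RPKM of at least 5. The simulated share alone was therefore not a sufficient bound. The simulated noise also held no GC trend, while the vector libraries deviated with GC content in opposite directions (-0.31 and 0.28). Leaving out 1 vector library cannot decide this, since the GC deviation of the other then stays in the fold. Target genes already near the floor could be a reason, since 46.2% of the listed PRC2-silenced genes (18 of 39) lay under the level filter, a share that neither requires nor excludes it. Uptake of the plasmid by a minority of cells stays open, since the 28.4-fold level of EZH2 is a mean over all cells and no value in a bulk table bears on its distribution.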

How the results depend on the processing

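Tests chosen after seeing the data were voom, scaling to reads in listed genes, the 2 length trends, the GC trend and the fit of the 6 EZH2 libraries; the cause of each move below was not tested unless stated. The EZH2 rise past the threshold stayed in 72 of 72 alternative values. Of the list calls, 525 alternative values kept their side of the threshold and 100 lost it, and of the folds of named genes 3269 kept their side, 340 lost it, 279 gained it and 1 changed sign, OCLN in T372A against wild-type EZH2. Gene counts moved by over 1.5 times in 74 of 159 alternatives. Depth limited genes under the level filter, and the lowest total of a tested gene was 7 reads.

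Without a filter on level, 6 genes passed for wild-type EZH2 against the vector, 10 for T372E against the vector, 8 for T372E against wild-type and 30 for T372E against T372A, and 4 lists passed for T372A against wild-type. There 8 passed for T372A against the vector and 17 for T372A against wild-type, but only 1 of the 11 and 8 of the 23 genes called with the filter were among them, and 14 of 66 for T372E against T372A. With a filter at RPKM 5, 25 genes passed for T372A against the vector, and the correlation of the wild-type and T372E changes was -0.12. With the GC trend removed, 90, 952 and 18 genes passed for wild-type, T372A and T372E against the vector, 161 for T372A against wild-type, 41 for T372E against wild-type (with 6 lists) and 412 for T372E against T372A.

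For T372A against the vector, 1 gene passed after median centring, without a trend in eBayes, with library weights, with only the 2 groups compared, at a fold of at least 1 on the log2 scale and with either length trend removed. It was 19 after quantile normalization, 69 at an adjusted p under 0.10 and 34 by voom. For T372E against the vector, 5 passed after quantile normalization and 10 by voom. For T372A against wild-type, 7 passed without a trend in eBayes, 199 with library weights, 79 with only the 2 groups, 3 at a fold of at least 1 on the log2 scale and 263 with the 6 EZH2 libraries. For T372E against wild-type, 834 passed with library weights, 914 with only the 2 groups and 1554 with the 6 EZH2 libraries, and 1 list passed with the trend with the longest transcript removed.

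For T372E against T372A, 18 passed after median centring, 30 after quantile normalization, 12 without a trend in eBayes, 1880 with library weights, 2186 with only the 2 groups, 280 at an adjusted p under 0.10 and 2 at a fold of at least 1 on the log2 scale. It was 30 by voom, 25 after scaling to the reads in listed genes, 18 and 19 with the trend with the length in the values or with the longest transcript removed, and 1584 with the 6 EZH2 libraries.

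Each library has its own number from 1 to 8, and 1 library of each group is among 1 to 4 and among 5 to 8; whether these sets were batches is not stated. Deviations from the group means correlated between groups from -0.25 to 0.48. They were positive among the vector, wild-type and T372E groups (0.48, 0.21 and 0.17) and negative with T372A (-0.25, -0.20 and -0.12). With 1 difference per group, these values neither show nor exclude a pairing of the samples by set. With the set as a replicate block, 1 gene passed for T372A against the vector and 38 for T372E against T372A, and the interferon list lost its call for T372A against wild-type (adjusted p = 0.076).

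With an estimated correlation in camera, 0 lists passed in each of the 6 comparisons. By fry, 9 lists passed for T372E against the vector and 5 for T372A against wild-type.

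Leaving out each library in turn, the gene counts ranged from 1 to 2213 for wild-type, 1 to 1892 for T372A and 1 to 1463 for T372E against the vector. They ranged from 7 to 272 for T372A against wild-type, 0 to 1563 for T372E against wild-type and 12 to 1618 for T372E against T372A; the highest came without vector replicate 2 in 5 of the 6 and without vector replicate 1 for T372E against the vector. The count of 0 is limma's with 1997 genes at an unadjusted p under 0.05 in the fit of all libraries and 0 by voom. List counts ranged from 1 to 5 for wild-type and 2 to 5 for T372E against the vector and from 2 to 9 for T372A against wild-type. The correlations ranged from 0.45 to 0.83 for wild-type with T372A, -0.04 to 0.62 for wild-type with T372E and 0.16 to 0.67 for T372A with T372E, and OCLN in T372A against wild-type from -0.008, without wild-type replicate 2, to 0.105.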

Other observations

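The fit of the 6 EZH2 libraries alone was chosen after the data were seen, and so were its genes; the respiratory chain group was assembled after its genes had been seen, its matched-list test was fixed before its result was seen, and its length-trend test was added later.

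Without the vector pair, 263 genes passed between T372A and wild-type EZH2 (48 rising, 215 falling), 1554 between T372E and wild-type EZH2 (703 and 851) and 1584 between T372E and T372A (1333 and 251). The chi-square between the reads of a pair, over its degrees of freedom, is near 1 for counting error alone. It was 3.13, 1.92 and 1.62 for wild-type, T372A and T372E EZH2 and 12.99 for the vector. With the widest pair left out after it was seen, the p-values below may be too small. USMG5, an ATP synthase subunit, rose with T372E against wild-type EZH2 (0.48, limma adjusted p = 0.013) and against T372A (0.50, 0.00073). MPG, a DNA repair glycosylase, fell with T372E against wild-type EZH2 (-0.97, 0.016), as did the cytokine MIF (-0.91, 0.024) and the complex I subunit NDUFB7 (-0.91, 0.026). Against T372A, T372E libraries had lower LRP1, an endocytic receptor (-0.51, 0.0076), and FASN, the fatty acid synthase (-0.54, 0.039), and higher MMP1, a collagenase (0.42, 0.012). Folds of T372E against the vector were 0.31 for USMG5, -0.58 for MPG, -0.40 for MIF, -0.31 for NDUFB7, -0.23 for FASN, -0.06 for LRP1 and 0.02 for MMP1, none of which passed. MMP1 stood at 9.99 and 11.4 RPKM with T372E, 11 and 10.1 with the vector and 7.9 and 7.85 with T372A, so the T372A libraries were the lower ones. FASN stood at 52.8 and 60.6 RPKM with T372E, between vector replicate 1 (49) and 2 (90.7). With T372A against wild-type EZH2, AHNAK (0.23, 0.019) and FKBP11 (0.39, 0.035) rose and RPS21 (-0.34, 0.015) fell.

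Genes that fell with T372E against wild-type EZH2 were GC-rich, with a median of 60.5% against 43.2% for those that rose and 47.8% for tested genes. With the GC trend removed the counts were 422, 770 and 921, of which 222, 548 and 643 were also called before. The folds were then -0.64 for MPG, -0.56 for MIF, -0.61 for NDUFB7, -0.41 for LRP1, -0.33 for FASN, 0.34 for MMP1 and 0.43 for USMG5, each still past the threshold. Vector replicate 1 and the T372E libraries lay on the same side of the GC trend (-0.31, -0.24 and -0.15 from the lowest to the highest decile). Wild-type replicate 2 lay on the other side (0.26), near vector replicate 2 (0.28), and wild-type replicate 1 at 0.03, so a trend of single libraries and an effect of T372E on GC-rich genes were not separated here.

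Nuclear-encoded respiratory chain transcripts, 72 tested genes, were lower with T372A than with the vector (64 negative, median -0.155, 0 past the threshold in limma) while the mitochondrially encoded ones were higher. The median was -0.149 against wild-type EZH2 (71 negative) and 0.15 for T372E against T372A, where 6 rose. Among 10000 random lists of 72 genes matched on length and level, its percentile was 0, which does not test the shift itself, since the group was chosen after its genes were seen. The lists had a median of -0.08 and the lowest reached -0.128 (-0.068 and -0.124 when matched on the longest transcript). With the trend with the length in the values removed the group stood at -0.132, and with that of the longest transcript at -0.143. Differences within groups reached 0.063 and 0.062 there. A shift of short transcripts may thus account for part of the value. Whether it accounts for all of it stays open, since the genes were seen before the group was assembled. Removing these trends also covers length only, not level. The nuclear fall was not particular to the respiratory chain. Ribosomal protein transcripts lay at -0.129 with T372A against the vector (31 of 32 negative) and at -0.178 against wild-type EZH2 (32 of 32 negative). A candidate explanation is that T372A EZH2 moves transcripts of the nuclear and the mitochondrial genome for the respiratory chain in opposite directions. That is a hypothesis found and tested on the same libraries. A wider shift of short or abundant nuclear transcripts and a difference between cultures stay open.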
